A study of Mus musculus with 2 samples.

How the data were processed

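DNase-seq was done on liver tissue of adult C57BL/6J mice after 62 hours of constant darkness, per the labels' descriptions. The labels name 2 libraries of 1 group, technical replicates 1 and 2 of biological replicate 1. All 7 measurement files describe the series as a whole, so there was no file per technical replicate to compare here. Per the notes deposited beside the files, they derive from 2 filtered alignments that are each listed under both libraries. One alignment gave the footprints, a pair of peak lists and a cut rate file, and the other gave the hotspots, a list of 150-bp peaks and a cut rate file. Coordinates are on mm10, per the same notes, and are given 1-based. The aligner, the peak caller and their versions are not given in the sources used here, nor is the sex of the animals or the total number of reads.

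The peak lists hold a signal per peak that the authors computed, with no statement of its scale in the sources used here. Every signal in both lists of the first alignment was a whole multiple of 0.00496 within 0.05 of that step, and the 150-bp list of the other alignment holds whole numbers. The deposited summit column holds the same number in every line, so peak midpoints were used. Hotspots carry a deposited score of up to 1000 and a deposited −log10 q value that ends at 100, reached by 13216 hotspots. Footprints carry 1 false discovery rate of 0.01, a q-value that the authors give for the whole file. The cut rate files hold, per the values the authors deposited, a false discovery rate (q-value) for each interval of 1 to a few bases, and only intervals under 0.05 are listed. Every peak value is the authors' own and was used only to describe, rank or filter peaks within a list.

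The main peak list was taken by a rule: the list tied to the footprints and hotspots by the notes, and otherwise the first by file name. The notes tie footprints and hotspots to different alignments, so the first by name was used, which belongs to the alignment of the footprints. No interval lay beyond the end of a chromosome of the GRCm38 reference, on which genes were placed with GENCODE M21. Overlap was counted from 1 bp. Locations were assigned by midpoint in the order promoter, exon, intron and intergenic, against as many random positions outside runs of unknown sequence.

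The 17 gene lists held 290 distinct genes, all of which were found in the annotation. A gene's promoter signal was that of the strongest peak within 1 kb of any of its annotated starts, or 0. Such a start can lie far inside the gene, as for the named peaks of Stab2, Por, Abcc2 and Rora. Random lists were drawn 10000 times from protein-coding genes in the same decile of CpG observed over expected, counted within 500 bp of the start. Distal peaks, over 1 kb from any annotated start, were counted within 50 kb and compared with random lists matched in 5 classes of gene density. A percentile counts random lists below the observed median plus 50% of the tied ones. Markers of other liver cells, blood cells and other tissues were among the lists.

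Consensus sequences of 32 motifs were searched on both strands in 150 bp around each midpoint. The background was 1 window per peak outside all peaks and hotspots, matched in 2% classes of GC content but not on CpG content. Footprints were widened by 5 bp to each side and compared with the same interval shifted by 50 bp within its hotspot, which was possible for 98.5% of them. The uniqueness of a peak's sequence was measured as the share of its 36-base words that occur once in the reference, on either strand. Bootstrap intervals used 2000 draws.

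The gene lists, motifs, designs, named-gene rule and most alternatives were fixed before the data were examined. Named genes are all core clock genes and, for every other list, the 3 members with the strongest promoter peak and up to 3 without one, in alphabetical order. Some genes that fall under this rule are not reported here. Named peaks are the 10 strongest. Named motifs are the 8 highest and 4 lowest ratios among motifs with 50 or more matching peaks, with the E-box, D-box and ROR and REV-ERB element. Alternatives were the other peak lists, the peaks at or above the median signal, other promoter windows and distal reaches, unmatched random lists, the 5′-most start, other window lengths, flanks 1 kb away, column-shuffled motifs, other thresholds and overlaps, and a shift of 100 bp. After the data were seen, a background without repeats, footprint controls that overlap no footprint, random lists for clock motifs matched on promoter signal and the leaving out of a run of weak peaks from the chromosome 1 region were added.

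With 1 group and 1 biological replicate, no test and no p-value is given. Shares have 95% exact Clopper-Pearson binomial intervals, which cover counting error only, as sequenced fragments are not independent molecules and peaks are not independent of each other. The gene list step was tested on simulated data: 60 random lists of 20 genes had a mean percentile of 55.0 with 2 above 97.5, and a planted list reached 100. In the same way, 60 random lists gave a mean percentile of 51.6 for E-box content, with 2 at or above 97.5. The motif search recovered 100% of consensus sites planted in 10.2% of 20000 simulated windows. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.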

Results

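DNase-seq maps open chromatin by sequencing the ends that the nuclease DNase I leaves where it reaches the DNA. Here it was applied to the liver of adult C57BL/6J mice, 8 to 10 weeks old, kept in constant darkness for 62 hours and sampled at Circadian Time 50, a time counted by the animal's own clock. The series holds 2 libraries of 1 group, labelled technical replicates 1 and 2 of biological replicate 1. Every measurement file describes the series as a whole, so there is no second condition, no biological replication and no test between groups. Shares carry 95% exact (Clopper-Pearson) binomial intervals and ratios 95% intervals on the log scale, and both cover counting error only. Gene lists are placed among 10000 random lists, which describes these libraries and is not a test over animals. Total read numbers are unknown from these files. The main list of 164659 peaks had a median of 182 signal steps per peak and a maximum of 21222, where 1 step is the amount of which every signal is a whole multiple, within 0.05 of a step. A step is not known to be 1 sequenced tag, so these numbers give no read depth.

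The main list covered 32.8 Mb, or 1.24% of the 2.65 Gb of assembled sequence, with a median peak width of 200 bp. The authors' hotspots, the broader domains of raised cutting, numbered 193093 and covered 85.0 Mb. Their footprints, short stretches protected from cutting inside open chromatin, numbered 442393 and had a median width of 9 bp. Of the main peaks, 99.5% (99.5 to 99.6) overlapped a hotspot, as did 99.05% (99.02 to 99.08) of the footprints, while hotspots covered 3.21% of the sequence. Peaks, hotspots and footprints were all called from the same libraries, so their nesting describes the calling and shows no enrichment. A footprint lay in 82.0% of the main peaks, rising from 36.9% in the weakest signal decile to 99.9% in the strongest. The mean number of footprints per peak rose from 0.494 to 4.23 over the same deciles. Stronger signal can make footprints easier to call, so this rise does not show that weak peaks are less often protected.

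The files derive from a pair of filtered alignments of the same libraries, and most main peaks had a counterpart in the other. Of the main peaks, 98.0% (97.9 to 98.0) were overlapped by a 150-bp peak of the other alignment, and the signals of overlapping peaks had a Spearman rho of 0.999 across peaks. In the other direction, 71.5% (71.3 to 71.7) of the 225849 peaks of the 150-bp list overlapped a main peak, and 93.7% overlapped a peak of the longer list. Peaks are not replicates, so this describes the processing and not the animals. The base-pair Jaccard index of the 150-bp list was 0.519 with the main list and 0.613 with the longer list. The positions with a raised cut rate at a false discovery rate of 0.05 covered 82.4 Mb in one alignment and 84.3 Mb in the other, with a Jaccard index of 0.912. The longer list of the main alignment held 219804 peaks. Of these, 57418 did not overlap the main list and had a median signal of 0.203, against 0.922 for the others.

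Open chromatin in this liver lay mostly away from gene starts, and the share at promoters was higher among stronger peaks. Promoters, here the windows of 1 kb to each side of a protein-coding transcription start site, held 20.1% (19.9 to 20.3) of the peaks but 3.73% of random positions. Introns held 38.6% of the peaks and 33.4% of random positions, exons 3.79% and 2.63%, and intergenic sequence 37.5% and 60.2%. The median signal was 1.66 at promoters, 0.858 in exons, 0.838 in introns and 0.758 between genes. The promoter share rose from 8.68% in the weakest decile of peak signal to 41.7% in the strongest, and to 60.8% among the top 1% of peaks, though of the 10 strongest peaks 1 lay at a promoter. Transposon-derived and other repeats made up 12.3% of peak sequence against 36.3% of sequence at random positions. Random positions were any assembled base, and whether reads can be placed there was not measured. The gap thus does not show that repeats are less open. The promoter share depended on the window and was 14.5% with 500 bp and 28.7% with 2500 bp to each side.

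**Figure D1:**
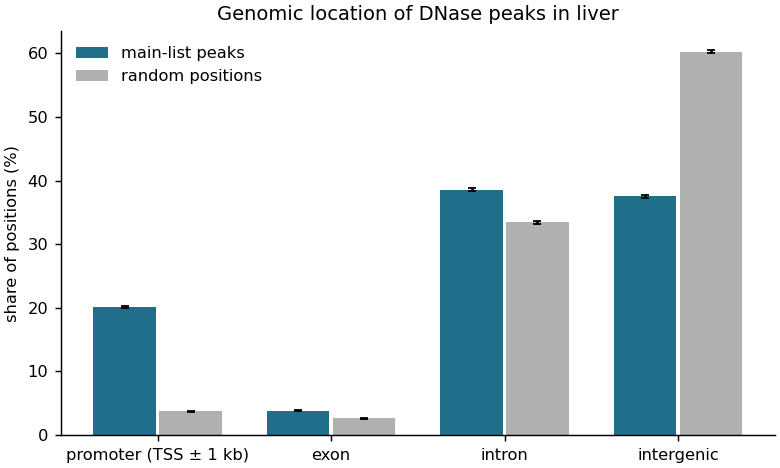
Share of the 164659 main peaks and of the same number of random positions (y axis, percent) at promoters, in exons, in introns and between genes, with 95% exact binomial intervals. Peaks lie at promoters in 20.1% of cases against 3.73% of random positions.

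Promoters rich in CpG dinucleotides were open far more often than CpG-poor ones. Of 21911 protein-coding genes, 14366 had a promoter peak, or 65.6% (64.9 to 66.2). The share rose from 16.8% (15.2 to 18.4) in the lowest decile of promoter CpG content to 94.9% (93.9 to 95.8) in the highest. For this reason each gene list below was set against random lists of genes from the same CpG deciles.

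The promoters of the circadian clock genes were open in this liver without exception. All 22 genes of the core clock list had a promoter peak, against a mean of 85.2% in matched random lists. Their median promoter signal was 9.82, against 4.47 in the random lists (central 95% of lists 2.27 to 6.91), and 0 of 10000 random lists reached it. Around them, the median number of distal peaks within 50 kb was 12 (quartiles 8.50 and 21.25), against 6 in random lists matched on gene density. Housekeeping genes, a list of general cell functions, also stood high, with a median signal of 8.34 that 10 random lists reached.

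The strongest clock promoters were those of Nr1d2, Per1, Nr1d1, Arntl and Dbp, which belong to the interlocked feedback loops of the clock and its output. Nr1d2, which encodes the nuclear receptor REV-ERB beta, had the highest signal of the list, 17.6, at a peak on chromosome 14 from 18239101 to 18239380 that spans the gene's start and holds 5 footprints. Per1, a period gene whose protein represses CLOCK and BMAL1, reached 14.8 in a peak on chromosome 11 from 69094781 to 69095240 with 8 footprints. Nr1d1, which encodes REV-ERB alpha, the repressor of Arntl, reached 14.7 in a peak on chromosome 11 from 98775281 to 98775720 with 9 footprints. Arntl, which encodes the activator BMAL1, reached 14.6 in a peak on chromosome 7 from 113207081 to 113207460 with 10 footprints. Dbp, an activator that binds D-boxes, had 12.6 on chromosome 7 from 45704781 to 45705040. Its relatives Tef and Hlf had signals of 11.4 and 8.03, and Nfil3, the repressor of the same sites, had 6.10.

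Among the other core members, the cryptochrome Cry2 had a promoter signal of 11.9 and Cry1 of 4.67. The nuclear receptor Rora had 4.19, the period genes Per2 and Per3 had 10.1 and 6.64, and the activator Npas2 had 10.0. The basic helix-loop-helix repressors Bhlhe40 and Bhlhe41 had 9.84 and 3.96, and the repressor Ciart had 9.14. Csnk1d had 5.59, Clock 3.94 and Csnk1e 1.42, the lowest value of the list; Csnk1d and Csnk1e encode casein kinases that phosphorylate period proteins. Distal peaks within 50 kb were most numerous at Nr1d1, with 28, at Per2, with 27, and at Bhlhe40 and Tef, with 25 each. Clock and Per3 had 4 each. With 1 circadian time, no value here separates a clock-driven signal from a constant one.

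**Figure D2:**
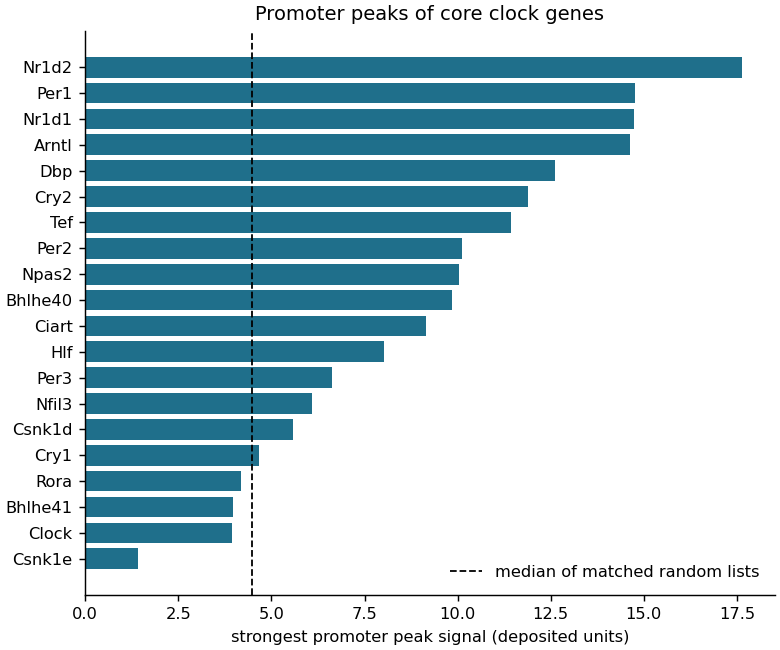
Strongest promoter peak signal (x axis, in the authors' signal units) of core clock genes, as bars, with the median of matched random lists as a dashed line. Values run from 1.42 at Csnk1e to 17.6 at Nr1d2, against a random median of 4.47.

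Genes that carry out the work of hepatocytes were open throughout, at their promoters and around them. All 25 plasma protein genes, 20 urea cycle and amino acid genes, 22 glucose and lipid genes, 20 bile acid and xenobiotic genes, 22 liver transcription factors and 20 rhythmic output genes had a promoter peak. Matched random lists had one at a mean of 42.6%, 53.1%, 64.4%, 37.7%, 70.8% and 59.9% of their genes. The median promoter signals were 8.73 for plasma proteins, 8.27 for urea cycle and amino acid genes, 9.36 for glucose and lipid genes and 6.49 for bile acid and xenobiotic genes. They were 8.52 for liver transcription factors and 8.13 for rhythmic output genes, while the matching random medians lay between 0 and 2.499. None of the 10000 random lists reached any of these 6 medians. With only the 5′-most start of each gene, a peak was found at 24 of 25, 20 of 20, 21 of 22, 18 of 20, 22 of 22 and 19 of 20 genes. These counts are in the order of the lists above. The medians then lay between 5.07 and 8.52, with 5.84 for rhythmic output genes, and at most 1 random list reached any of them.

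The plasma protein genes had the most distal open chromatin, with a median of 30 peaks within 50 kb (quartiles 17 and 43) against 6 in random lists. Apoa2, an apolipoprotein of high-density lipoprotein, had a promoter signal of 15.01. C3, the central component of complement, had 13.3 and 53 distal peaks. Fgg, the gamma chain of fibrinogen, had 12.1 and 57 distal peaks. Its neighbours Fga and Fgb, also in the list, lie in the same stretch of 100 kb, which holds 66 peaks. Such neighbours can count the same distal peaks. Liver transcription factors had a median of 22.5 distal peaks, and their strongest promoters were Esrra at 13.6, a nuclear receptor of energy metabolism, Nr5a2 at 12.9, a regulator of bile acid synthesis, and Nr0b2 at 12.4, a corepressor in the same pathway. Bile acid and xenobiotic genes had a median of 20 distal peaks. Abcc2, an export pump of the bile canaliculus, had a promoter signal of 14.4, Por, the electron donor of cytochromes P450, 14.01, and Cyp8b1, the sterol 12-alpha-hydroxylase, 10.7.

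Among urea cycle and amino acid genes, with a median of 16.5 distal peaks, Uroc1, which encodes urocanate hydratase of histidine breakdown, had the strongest promoter at 16.1. Gls2, the liver glutaminase, had 12.1, and Tdo2, which opens the tryptophan ring, had 12.0. Among glucose and lipid genes, with a median of 15 distal peaks, Acly, which makes cytosolic acetyl-CoA, had 13.4, and Cpt1a, which admits fatty acids to the mitochondrion, had 13.2. The rhythmic output list, with a median of 16 distal peaks, was led by Angptl4, an inhibitor of lipoprotein lipase, at 16.5, by Por at 14.01 and by Gys2, the liver glycogen synthase, at 12.2. The lists share members, Por among them, so they are not independent of each other. The distal medians of the 6 lists were each reached by 0 of 10000 random lists, and that of the core clock by 3. Random lists were drawn gene by gene and not matched on neighbouring members. For lists that hold neighbours, these counts may overstate how unusual the list is.

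**Figure D3:**
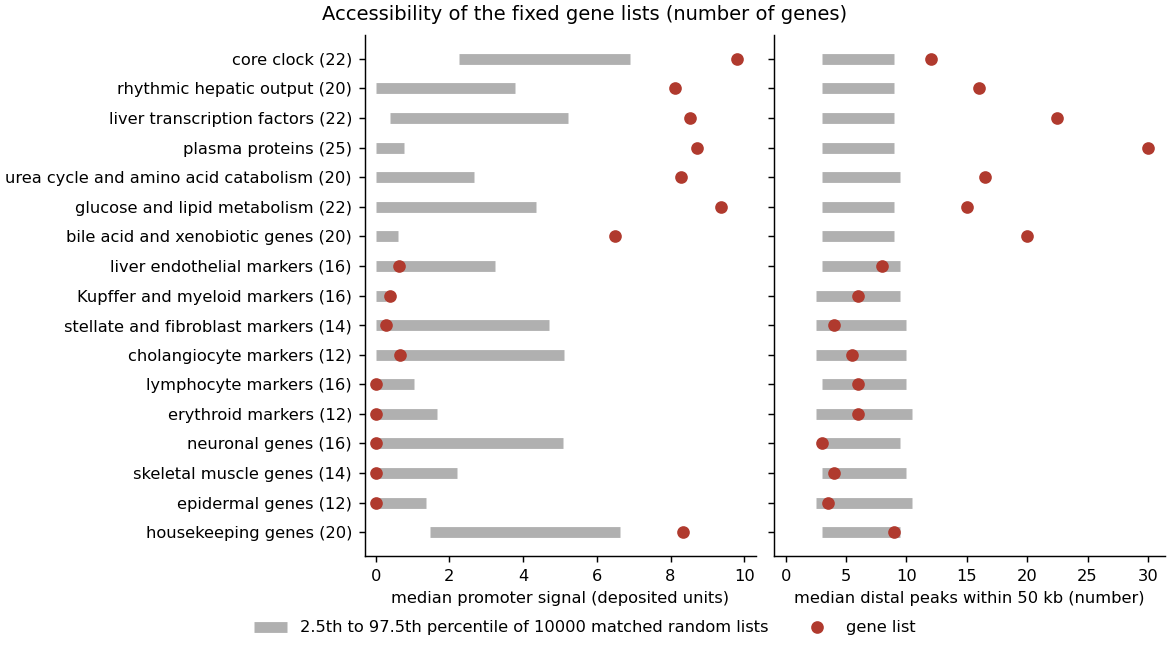
Median promoter peak signal (first x axis, in the authors' signal units) and median number of distal peaks within 50 kb (second x axis) of each of the 17 gene lists, as points, with the central 95% of 10000 matched random lists as bars. Core clock and hepatocyte lists lie beyond the bars for both measures, with plasma proteins at 8.73 and 30, and markers of other cell types lie within the bars for distal peaks.

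Markers of the other liver cells were open in part and at lower signal than the lists of hepatocyte function. Liver endothelial markers had a promoter peak at 14 of 16 genes, a share that 35 of 10000 random lists reached, with a median signal of 0.630. Kupffer and myeloid markers had one at 13 of 16 genes, a share that 1 random list reached, with a median signal of 0.379. Stellate and fibroblast markers had one at 9 of 14 genes and cholangiocyte markers at 7 of 12, with median signals of 0.270 and 0.657. The medians of the 6 lists of hepatocyte function lay between 6.49 and 9.36. Matched random lists had median signals of 0.429 for endothelial, 0 for Kupffer and myeloid, 1.02 for stellate and fibroblast and 1.16 for cholangiocyte markers. Against random lists not matched on CpG content, 523 of 10000 reached the endothelial share and 1494 the Kupffer and myeloid share. With only the peaks at or above the median signal, 5 of 16 endothelial and 2 of 16 Kupffer and myeloid genes had a promoter peak, shares that 9215 and 8768 matched lists reached. Larger peak lists raised the shares: with the 150-bp list, 16 of 16 endothelial, 14 of 16 Kupffer and myeloid and 13 of 14 stellate and fibroblast genes had one, which 1, 0 and 158 matched lists reached, and with the longer list 15 of 16, 15 of 16 and 12 of 14. Genes said below to have none lacked a promoter peak in the main list.

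The strongest endothelial promoters were Stab2, a scavenger receptor of sinusoidal endothelium, at 5.15, Tie1, an endothelial receptor kinase, at 4.22, and Fcgr2b, an immunoglobulin receptor, at 1.54. The Stab2 peak, from 86878821 to 86879020, lay at a start inside the gene, whose 5′-most start is at 87008025. With only the 5′-most starts, 12 of 16 endothelial genes had a peak, with a median signal of 0.364. Lyve1, a hyaluronan receptor, and Stab1, a scavenger receptor, had none, though Stab1 had 0.659 in the longer list. Among Kupffer and myeloid markers, Cd68, a lysosomal glycoprotein of macrophages, had 1.18, Spi1, which encodes the myeloid factor PU.1, 0.917, and C1qa, a chain of complement C1q, 0.773. Adgre1, which encodes the F4/80 antigen, Csf1r, the receptor for macrophage growth factor, and Itgam, the integrin CD11b, had no promoter peak in the main list. Pdgfra, a growth factor receptor of mesenchymal cells, had 2.39, the collagen gene Col1a1 2.05 and Reln, a secreted glycoprotein of stellate cells, 1.11. Acta2, smooth muscle actin, the collagen gene Col3a1 and Des, the intermediate filament desmin, had none. Sox9, a transcription factor of biliary cells, had 7.86. Ehf, an epithelial ETS factor, had 3.93. Cftr, the chloride channel, Cldn7, a tight junction protein, and Krt19, a biliary keratin, had none.

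In the longer list, Adgre1 had a promoter peak of 0.476, Csf1r of 0.208, Des of 0.283, Col3a1 of 0.198 and Cftr of 0.109. Signal at the Kupffer and myeloid list stood at percentile 98.4 of matched random lists. It fell to percentile 14.8 against random lists not matched on CpG content and to 49.6 with only the peaks at or above the median signal.

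Markers of blood cells and of tissues other than liver had no promoter peak in the main list at most of their genes. Lymphocyte markers had a promoter peak at 6 of 16 genes, erythroid markers at 5 of 12, neuronal genes at 7 of 16, skeletal muscle genes at 5 of 14 and epidermal genes at 2 of 12. The median signal was 0 in all 5 lists. Matched random lists had a peak at a mean of 40.4%, 41.6%, 65.3%, 47.2% and 40.1% of their genes, so the lymphocyte and erythroid shares were close to those of matched lists. Against random lists not matched on CpG content they were low, as 9948 of 10000 reached the lymphocyte share and 9762 the erythroid share. With promoter windows of 2500 bp, a peak was found at 8 of 16 lymphocyte, 6 of 12 erythroid, 9 of 16 neuronal, 6 of 14 skeletal muscle and 5 of 12 epidermal genes, and the 150-bp list also had one at 9 of 16 neuronal genes. With windows of 500 bp the counts were 4 of 16, 5 of 12, 4 of 16, 3 of 14 and 1 of 12, in the same order, and with only the peaks at or above the median signal 2 of 16, 2 of 12, 1 of 16, 4 of 14 and 1 of 12. The neuronal shares in these last 2 comparisons were reached by 9999 and 10000 of 10000 matched lists. In the main setting the neuronal share was reached by 9911, and with windows of 2500 bp by 9572. The neuronal median signal stood at percentile 1.80 and moved to between 2.80 and 11.4 under the 7 alternative settings.

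The lymphocyte kinase gene Lck had the highest lymphocyte signal, 3.24, followed by the B-cell factor gene Pax5 at 1.58 and Cd3d, a chain of the T-cell receptor complex, at 0.620. The receptor chain genes Cd3e and Cd3g had none. Sptb, which encodes erythroid spectrin beta, had 1.22, and Alas2, which starts heme synthesis in red cells, 0.684. Ermap, an erythroid membrane protein, Gata1, the master factor of red cells, and Hemgn, a hematopoietic nuclear protein, had none. Of neuronal genes, the synaptic vesicle gene Syn1 had 2.05, Snap25, of vesicle fusion, 0.858 and Gad2, a GABA-making enzyme, 0.590. Camk2a, a synaptic kinase, Dlg4, a postsynaptic scaffold, and Grin1, a glutamate receptor subunit, had none, though Dlg4 had 0.292 in the longer list. Mylpf, a fast muscle myosin light chain, stood apart from the muscle list with 11.6 at a CpG-rich promoter of decile 9. The myosin gene Myh4 had 2.93 and Ckm, muscle creatine kinase, 2.07, while the actin gene Acta1, the calcium pump gene Atp2a1 and the myoglobin gene Mb had none. Krt10, an epidermal keratin, had 3.02 and Lor, of the cornified envelope, 0.169. The desmosomal cadherins Dsc3 and Dsg3 and the filament-binding gene Flg had none. The strongest housekeeping promoters were Vcp, an ATPase of protein turnover, at 11.2, the elongation factor gene Eef1a1 at 11.1 and the ribosomal gene Rplp0 at 11.1.

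The HNF1, CEBP, DR1 and HNF4A sites of hepatocyte transcription factors were many times more frequent in open chromatin than in GC-matched closed sequence, though by how much depended on the comparison. The site of HNF1, a homeodomain regulator of plasma protein genes, occurred in 478 peaks, a ratio of 29.9 (18.2 to 49.2) over background windows, of which 16 held it. The CEBP site, bound by the C/EBP factors of liver metabolism, occurred in 805 peaks, a ratio of 17.5 (13.003 to 23.6). The DR1 element of PPAR-RXR, the fatty acid sensors, had a ratio of 15.2 (9.02 to 25.6). Its consensus ends in a full match to the HNF4A consensus, so every DR1 match, in peaks or footprints, is also an HNF4A match. The HNF4A site, bound by the nuclear receptor that maintains the hepatocyte state, was the most widespread of these, in 7868 peaks or 4.78%, with a ratio of 6.20 (5.85 to 6.58). Against flanks 1 kb away from the same peaks, the ratios were lower, at 5.56 (4.67 to 6.62) for HNF1, 8.09 for CEBP, 8.77 for DR1 and 4.86 for HNF4A. In 300-bp windows they were 9.73, 8.93, 6.44 and 3.81, in the same order, and in 50-bp windows 46.8, 55.0, 27.8 and 10.2. Against column-shuffled versions of their own consensus they were 14.1, 1.0996, 69.1 and 9.06, so the CEBP ratio rests on the comparison with closed sequence and flanks. The CEBP consensus holds a CpG, and neither closed windows nor flanks were matched on CpG content. Part of its ratio may reflect that content, which was not tested. Other liver factors had lower ratios over closed sequence, with ONECUT at 5.67 (5.26 to 6.11), FOXA at 2.88 (2.75 to 3.01) and NR5A2 at 2.79 (2.52 to 3.08), and with 3.34, 2.01 and 2.16 against flanks. These 3 were outside the rule for named motifs and chosen after their values were seen.

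Other sites with high ratios were the full NFI palindrome at 11.2 (6.49 to 19.4), NRF1, of nuclear genes for mitochondrial proteins, at 13.95 (9.05 to 21.5), and ETS, of many basal promoters, at 5.95 (5.16 to 6.87). The highest ratio, 35.5 (8.71 to 145), was that of REST, the repressor of neuronal genes, from 71 peaks against 2 background windows. Its share fell from 0.158% of peaks in the weakest signal decile to 0 in the strongest, and its ratio was 3.67 (1.02 to 13.1) among peaks at or above the median signal. Over all 32 motifs, 19 had a ratio of 2 or more. Of the clock-related sites, the D-box of DBP, TEF and HLF had a ratio of 3.29 (2.98 to 3.63), the ROR and REV-ERB element 2.51 (2.30 to 2.74) and the E-box CACGTG of CLOCK and BMAL1 1.957 (1.88 to 2.04), in 3.97% of peaks. Against flanks 1 kb away, the D-box had 1.51 (1.41 to 1.60), the ROR and REV-ERB element 2.09 and the E-box 1.94, and NRF1 had 4.99. The NRF1, ETS and E-box consensuses also hold a CpG, as does the D-box consensus TTAYGTAA where Y is C. The limit given for CEBP applies to all of them.

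The ratios were also computed apart for promoter-proximal and distal peaks. NRF1 had a ratio of 32.1 (15.9 to 64.9) in promoter-proximal peaks and 6.25 (2.96 to 13.2) in distal ones, and ETS 16.9 (12.9 to 22.2) and 2.01 (1.68 to 2.39). In the same order, HNF4A had 3.63 (3.12 to 4.22) and 6.58 (6.17 to 7.01), and CTCF, the insulator protein, 1.48 (1.37 to 1.60) and 8.62 (8.14 to 9.12). OCT had 2.23 (1.79 to 2.79) and 0.829 (0.761 to 0.904). The intervals of DR1, 4.75 (1.62 to 13.96) and 17.4 (9.73 to 31.2), overlapped. CTCF was outside the rule for named motifs and was chosen after its values were seen. The difference between these ratios was not tested, and the windows were not matched on CpG content.

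The 4 lowest ratios among motifs with at least 50 matching peaks were NFY, the CCAAT box, at 1.11 (1.098 to 1.13), the neuronal NEUROD site at 0.965 (0.920 to 1.01), the OCT site at 0.941 (0.870 to 1.02) and YY1 at 0.397 (0.375 to 0.420). The YY1 ratio rose to 1.17 (1.09 to 1.25) when background windows held no repeat, a background with which REST, DR1 and NRF1 had ratios of 17.8, 8.44 and 7.31. Set against column-shuffled versions of their own consensus, the E-box fell to 1.06, the D-box to 1.48, ETS to 1.85 and NFI to 4.83, while NEUROD, OCT and YY1 rose to 2.54, 1.47 and 2.95.

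**Figure D4:**
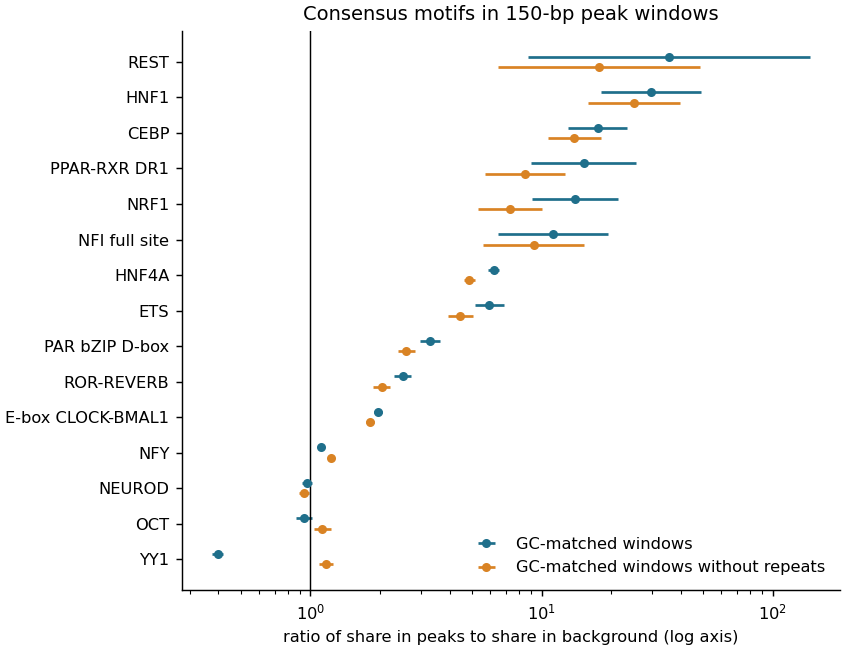
Ratio of the share of main peaks with a consensus match to the share of GC-matched background windows (x axis, log scale) for the 15 named motifs, with 95% intervals for counting error, and the ratio against background windows without repeats. HNF1 stands at 29.9, and YY1 at 0.397 or, without repeats, 1.17.

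Many of the same sites were more frequent in footprints than in shifted intervals of the same hotspots. The shifted intervals were not matched on base composition or on distance from the peak's midpoint. The sequence preference of the nuclease was not modelled here, so a ratio is not shown to come from a bound factor. Of 435909 footprints with a control interval in their own hotspot, 56065 or 12.9% held any of the 32 motifs. The same share was not computed for control intervals. The short NFY consensus alone matched 4.29% of footprints and 3.13% of control intervals, so many such matches also occur beside footprints. NFI sites were 12.3 (6.25 to 24.3) times as frequent in footprints as in intervals shifted by 50 bp, and CTCF sites 7.39 (6.96 to 7.84) times. The DR1 element had a ratio of 5.67 (3.76 to 8.53), HNF1 3.76 (2.84 to 4.97), CEBP 3.71 (3.13 to 4.40), NRF1 3.63 (2.92 to 4.53) and HNF4A 3.26 (3.08 to 3.46). Of the clock-related sites, the D-box had 2.01 (1.78 to 2.26), the E-box 1.69 (1.60 to 1.78) and the ROR and REV-ERB element 1.24 (1.08 to 1.43). REST sites occurred in 26 footprints and 0 control intervals.

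Some sites were less frequent in footprints than beside them, where the same limit on base composition and nuclease preference applies. The glucocorticoid receptor site had a ratio of 0.194 (0.0808 to 0.464), GATA 0.482 (0.433 to 0.536), FOXA, of the liver pioneer factors, 0.569 (0.526 to 0.616) and OCT 0.607 (0.514 to 0.718). Of these, OCT fell under the rule for named motifs, and the others were chosen after their values were seen. ETS, YY1, NEUROD and NFY had ratios of 1.496, 1.58, 1.41 and 1.37. Controls lie in the same hotspot and can hold footprints of their own. With controls that overlapped no footprint, NFI had 36.5, CTCF 20.4, DR1 45.5, HNF1 10.0, CEBP 11.4, NRF1 52.0 and HNF4A 5.58. With controls shifted by 100 bp the ratios were 13.5, 18.7, 16.8, 5.83, 7.77, 6.67 and 5.35, in the same order. The ROR and REV-ERB ratio was 0.860 (0.572 to 1.29) in promoter-proximal hotspots, from 43 footprints and 50 controls, so no direction is shown there.

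Peaks were spread over all autosomes and were sparse on the sex chromosomes. The 19 autosomes together had 67.0 peaks per Mb, from 52.6 on chromosome 14 to 94.9 on chromosome 19. Chromosome X had 4076 peaks, or 24.9 per Mb, with a median signal of 0.471, below that of every autosome; the lowest autosomal median was 0.808, on chromosome 1. Chromosome Y had 51 peaks, or 0.579 per Mb. How much of the Y sequence occurs once in the reference was not measured, so few peaks there are not shown to mean closed chromatin. Of 183 protein-coding genes on Y, 4 had a promoter peak: Uty and Kdm5d, which encode histone demethylases, at 4.79 and 1.83, Ddx3y, an RNA helicase, at 3.01, and Eif2s3y, a translation factor, at 2.26. The sex of the animals is not given in the sources used here.

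Of the 10 strongest peaks, 4 lay within 100 kb of chromosome 1 over the Ugt1a cluster, which encodes bilirubin and drug conjugating enzymes, and over Hjurp and Trpm8. Hjurp encodes a chaperone of centromeric histone and Trpm8 a cold-sensing channel. These were peaks from 88288181 to 88288380, with a signal of 86.9, and from 88279201 to 88279320, with 39.98, both in an intron of Trpm8. The others were at the promoter of Hjurp from 88277501 to 88277760, with 44.1, and in an intron of the Ugt1a genes from 88213721 to 88213940, with 34.7. All 36-base words of these 4 peaks occur once in the reference. Extra copies of the region in the sampled genome would not show in this measure. The test of such copies, given at the end, could not tell.

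The remaining 6 hold sequence found elsewhere, so their height can include reads from other places. The strongest peak of all, 105, lay in an intron of the importin gene Kpna1 on chromosome 16 from 35981641 to 35981800, and 57.6% of its 36-base words occur once. A peak of 88.4 in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase, on chromosome 9 from 123461981 to 123462060 had 15.6% of such words. Intergenic peaks on chromosome 1 stood at 60.9 from 195241541 to 195241800, nearest to the complement receptor gene Cr2, and at 38.7 from 122357141 to 122357300, nearest to the helicase gene Ddx18, with 76.0% and 81.6%. A peak of 56.7 in an intron of Jarid2, a Polycomb component, on chromosome 13 from 44869561 to 44869700 had 75.2%. An intergenic peak of 34.9 on chromosome X from 143483001 to 143483140, nearest to the kinase gene Pak3, had 78.1%.

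**Figure D5:**
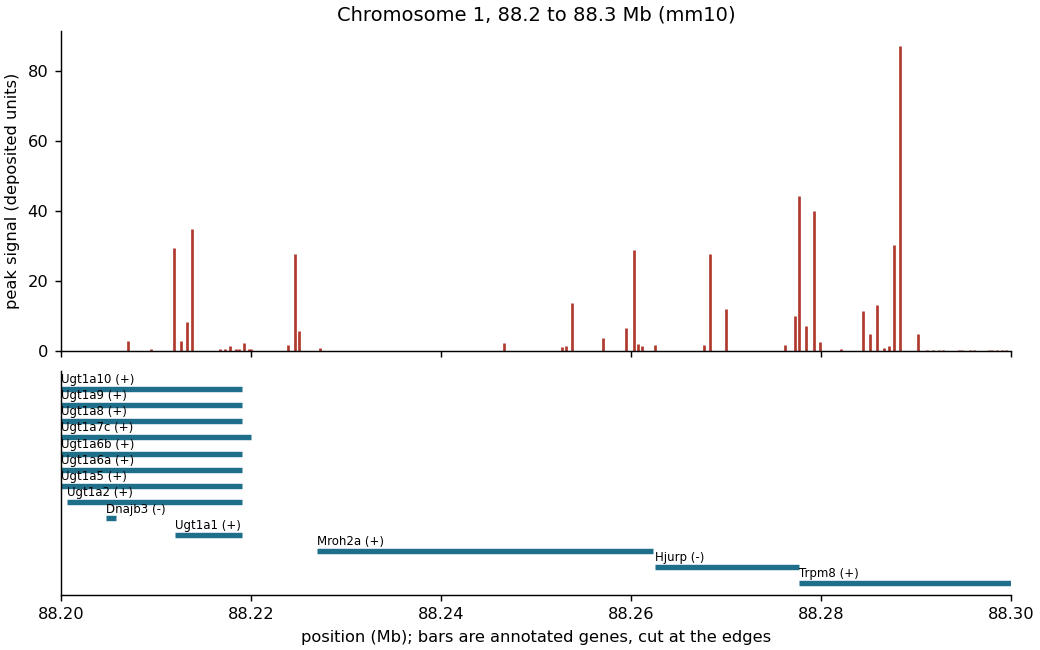
Signal of the 60 main peaks in a 100-kb window of chromosome 1 (x axis, position in Mb, and y axis, peak signal in the authors' units), above the genes of the window. Signals run from 0.129 to 86.9, with the 4 peaks among the strongest of the genome over the Ugt1a cluster, Hjurp and Trpm8. Extra copies of the region in the sampled genome were not excluded.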

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

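The background without repeats, the footprint controls that overlap no footprint, the matching of clock motif lists on promoter signal and the leaving out of a run of weak peaks on chromosome 1 were the tests chosen only after results were seen. No paired analysis was possible because the series has 1 group and no result comes from a test. Leaving out each technical replicate was not run, since no file per technical replicate was used here. Of 443 values under alternative settings, 396 kept their direction and side of the threshold, or stayed within their interval or within 1.5 times a count, 11 became weaker, 11 stronger, 16 moved beyond their interval and 9 reversed.

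The number of gene lists in the top 2.5% of random lists, with ties counted as 50%, was 9 for promoter signal (8 to 9 under alternatives) and 7 for distal peaks (7 to 8). Core clock, rhythmic output, liver transcription factor, plasma protein, urea cycle, glucose and lipid, bile acid and housekeeping lists stayed there for promoter signal in all 7 alternatives. The number of motifs at a ratio of 2 or more was 19 in peaks (16 to 21) and 12 in footprints (12 to 15). Taking only peaks at or above the median signal left 82582 peaks by construction. Shared main peaks were 87.95% when 50% of both intervals had to overlap and 99.9% among peaks at or above the median. The cut rate Jaccard index was 0.909 and 0.905 at false discovery rates of 0.01 and 0.001. Peaks lying in hotspots were 98.7% when wholly inside, 96.6% for the longer list and 99.9987% for the 150-bp list, and footprints wholly inside were 98.9584%. The promoter share was 14.5% and 28.7% with windows of 500 and 2500 bp, 23.5% with the starts of all annotated genes, 17.7% and 17.5% with the longer and the 150-bp list, and 26.3% for peaks at or above the median.

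Reversals were few. The Kupffer and myeloid list went from percentile 98.4 to 14.8 with unmatched random lists and to 49.6 with peaks at or above the median, where more of its genes count as 0. NEUROD rose to 1.09 in 50-bp windows and 2.54 against shuffled motifs, OCT to 1.13 with a background free of repeats and 1.47 against shuffled motifs, and YY1 to 1.17 and 2.95 in the same comparisons. The main intervals of NEUROD and OCT spanned 1. The ROR and REV-ERB footprint ratio was 0.860 in promoter-proximal hotspots, with an interval (0.572 to 1.29) that spans 1, so no turn of direction is shown. The cause was not tested for NEUROD, OCT, ROR and REV-ERB, YY1 against shuffled motifs or the unmatched Kupffer value. REST had no value in 50-bp windows, where the background held no match, and no ratio over all footprints, where no control held one; its peak ratio ran from 3.67 with peaks at or above the median to 710 against shuffled motifs. Among weaker values, the neuronal percentile of 1.80 went to between 2.80 and 11.4 in all 7 alternatives, the Kupffer and myeloid percentile to 93.6 with windows of 2500 bp, CEBP to 1.0996 against shuffled motifs, NFY to 1.00 in 300-bp windows and NEUROD in promoter-proximal footprints to 1.09. Among stronger ones, distal peaks around liver endothelial markers reached percentile 97.7 and 98.1 with reaches of 20 and 100 kb, and those around housekeeping genes 99.8 with peaks at or above the median. Read depth is unknown here. The weakest peak of the main list held 10 steps of signal, and a gene without a peak in it is not shown to be closed.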

Other observations

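In what follows, the comparison of YY1 with flanking sequence, the matching of clock motif lists on promoter signal and the leaving out of a run of weak peaks on chromosome 1 were the tests chosen only after the result was seen, and the background without repeats was added once the low YY1 ratio had been seen.

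The number of peaks per stretch of 100 kb varied widely along the genome. Of 20188 stretches of 100 kb with a peak, the median held 6 peaks and the 99th percentile 34. The densest, on chromosome 19 from 5800001 to 5900000, held 84 and contains Frmd8, Slc25a45, Tigd3 and Dpf2. Next came stretches on chromosome 2 from 103400001 with 71 peaks, over the catalase gene Cat and the ETS factor gene Elf5, on chromosome 9 from 103200001 with 70, over the transferrin gene Trf, and on chromosome 7 from 99100001 with 69, over Uvrag, of autophagy, and Dgat2, of triglyceride synthesis. Ppara, the fatty acid sensor, lies in a stretch of chromosome 15 with 68 peaks, and the 3 fibrinogen genes Fga, Fgb and Fgg in one of chromosome 3 with 66. These stretches were chosen by their peak number after the data were seen.

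The strongest single promoters outside the chromosome 1 region, chosen after their values were seen, were those of Ankhd1, an ankyrin repeat protein, at 23.1, Snrnp70, a splicing factor, at 20.8, Hbp1, a transcriptional repressor, at 20.6, and Slc25a28, a mitochondrial iron carrier, at 20.4. Between the weakest and the strongest signal decile, the share of peaks with an NRF1 site went from 0.0364% to 0.911%, that with an SP and KLF site from 0.698% to 5.89%, that with an E-box from 2.33% to 6.35%, and that with a site of PU.1, a myeloid factor, from 1.26% to 0.377%. The share of peaks at promoters went from 8.68% to 41.7% over the same deciles, and NRF1 and SP and KLF sites had higher ratios in promoter-proximal peaks (32.1 and 3.26) than in distal ones (6.25 and 1.65). The decile differences were not tested apart from that of location.

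The clock promoters were tested for clock binding sequences, with the hypotheses written before the counts were made. The E-box CACGTG occurred in the promoter peaks of 13 of 22 core clock genes, among them Per1, Nr1d1, Nr1d2, Dbp, Tef and Ciart, against a mean of 6.32 in lists of open promoters matched on total peak length and CpG content, percentile 99.84, with 25 of 10000 lists as high. The D-box occurred at 4 genes, Per2, Per3 and Nr1d2 among them, against a mean of 0.865, percentile 99.395, with 105 lists as high. The ROR and REV-ERB element occurred at Clock, Npas2 and Dbp, 3 genes against 0.790, percentile 97.66, with 404 lists as high, a count equal to the upper bound of the central 95% of random lists. The E-box and D-box values, and less clearly this one, fit the hypothesis that the open clock promoters may carry the sites through which clock factors regulate each other, though binding was not measured. Clock promoters have strong peaks, and strong peaks hold the E-box more often. In lists matched on promoter signal as well, with a typical median signal of 9.38 against 9.82 for the clock, the percentiles were 99.87 for the E-box, 99.395 for the D-box and 98.115 for the ROR and REV-ERB element. Footprints covered an E-box 5 times at Tef and 3 times each at Per1, Nr1d2 and Ciart. The Arntl peaks held no match to the ROR and REV-ERB consensus used here.

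A second hypothesis was that the open promoters of plasma protein genes carry the HNF1 site more often than matched promoters. No excess was seen, but the count could hardly decide the question. None of the 25 genes had a full HNF1 consensus in a promoter peak, percentile 42.56. Matched lists held it at a mean of 0.162 genes (central 95% 0 to 1), so 0 is close to what any such list gives. An HNF4A site was in 7 of the genes, percentile 97.395. Over all 102 combinations of gene list and motif, 6 were in the top 2.5% of random lists with ties counted as 50%, of which 3 are those of the core clock; the others were the D-box at rhythmic output genes, with Alas1, Wee1 and Usp2, whose 3 genes also only equal the upper bound of the central 95%, and HNF1 at glucose and lipid genes and at cholangiocyte markers, with Pkhd1. Chance alone gives some such combinations in a family of this size.

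The YY1 consensus was rarer in peaks than in GC-matched closed sequence, at a ratio of 0.397. Against background windows without repeats the ratio was 1.17 (1.09 to 1.25), which is consistent with repeats in the background carrying the consensus. A lack of the site against the peaks' own surroundings is argued against only as the whole cause: the ratio to flanks 1 kb away was 0.898 (0.847 to 0.951), so a small deficit remained there and stays open. The design gives no biological explanation to test, and most of the low ratio may be technical.

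Peak signal was lower on chromosome X than on the autosomes. The median promoter signal of the 427 X genes with a promoter peak was 2.51, against 4.84 for 13935 autosomal genes, and matched on CpG decile the ratio was 0.552 (0.492 to 0.626), which argues against a lower CpG content of X promoters as the whole cause. Over peaks whose 36-base words all occur once, the ratio was 0.529 (0.490 to 0.565), which argues against shared sequence. The ratio of 0.552 lay within the range of 0.4 to 0.65 set for a single X. By the ratio alone, a male or mostly male sample may account for it, but a female sample with a single active X may as well. The ratio thus cannot tell the sex. The promoter peaks at Uty, Ddx3y, Eif2s3y and Kdm5d on Y had signals of 4.79, 3.01, 2.26 and 1.83, against the median of 2.51 on X. They argue against a sample of females only, and for a Y chromosome in at least part of the sample. Whether reads at these peaks could come from similar sequence elsewhere was not measured. The lower X median had been seen before these tests, the sex is not given in the sources used here, and dosage was not tested apart from copy number.

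The cluster of 4 very strong peaks on chromosome 1 was weighed against mapping and copy number, and all of their 36-base words, 100%, occur once in the reference, which argues against reads shared with other places in it. Extra copies of the whole region in the sampled genome would raise all of its peaks. Of the 60 peaks, 36.7% (24.6 to 50.1) lay under the median of all peaks, and the interval spans the bound of 25. Copies could also bring sites otherwise too weak to be called into the list as weak peaks, so this share cannot decide the question. Extra copies cannot be told apart here from strong local openness with the peaks of 1 region. The share depends on where the region ends: its last 14 peaks, from 88290921 to 88299860, all lay under the median, at 0.129 to 0.426, and of the 46 others 8 did, or 17.4% (7.82 to 31.4). The median of the region was 1.64, against 0.962 for 157 peaks in the 500 kb to each side, where the highest was 9.47. Copies of a part of the region, or of sequence absent from the reference, remain possible and were not tested.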
